A study of Mus musculus with 9 samples.

How the data were processed

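Bulk RNA sequencing of right ventricular myocardium was analysed in 9 mouse libraries, grouped by the labels into Sham, VO and CsA with 3 libraries each. RNA was extracted with Trizol and libraries were built with a NEBNext Ultra kit, per the labels' protocols. The deposited table gives FPKM, fragments per kilobase of gene scaled to library size, for each gene and library, as the authors computed them. HISAT2 2.0.5, StringTie 1.3.3b, featureCounts 1.5.0-p3, DESeq2 1.20.0 and GATK 3.7 are named, with the builds GRCm38 and mm10 and with no role given, per the submitters' processing notes. The annotation release is not given in the sources used here, and whether counting used strand is not given either, so it is not known whether overlapping and antisense genes share reads.

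FPKM is not a count, so the main test ran on a log scale. Low values were whole multiples of what 1 fragment is worth in each library: 100% of values came out within 0.1 of a whole fragment. The recovered totals were 14280786, 13918019 and 13270058 fragments in Sham 1 to 3, 15363492, 12050425 and 15986747 in VO 1 to 3 and 12046288, 12941571 and 12725432 in CsA 1 to 3. The authors' denominators were 0.956 to 1.078 times these totals. Intervals and floors cover counting error only, since PCR copies cannot be told from separate molecules. Replicates were compared before averaging: a chi-square per degree of freedom over genes lay between 13.1 and 31.2 for pairs in a group without VO 3 and at 219.6 and 158.4 for VO 3 against VO 1 and VO 2, so no pair agreed within sampling noise.

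Values were transformed to log2(FPKM + 1), so a fold change is on the log2(value + pseudocount) scale and understates the change of low genes. Genes with a mean of at least 0.5 FPKM over the 9 libraries were kept (13477 of 54532; 27959 were at 0 in every library). All 9 libraries entered 1 fit in limma 3.58.1 under R 4.3.3, with a mean-variance trend in the empirical Bayes step and no covariate, and Benjamini-Hochberg adjustment at 0.05 within each comparison, two-sided. Gene lists were tested with limma's camera at a preset correlation of 0.01, for the 39 of 45 lists with at least 5 tested members, with adjustment over lists. The test was repeated with a correlation estimated per list and with fry. Scores per library were compared with an exact two-sided permutation test, whose smallest p for 3 against 3 is 0.1.

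The groups, the lists, the main tests, most alternatives and the rule for named genes were fixed before the data were examined. The rule took, per comparison, genes past the test with a symbol, protein coding, at least 2 FPKM in the higher group and no overlap between the libraries, the 8 highest and the 8 lowest by fold. Where fewer than 5 passed in a direction, the genes with the smallest p under the same level and symbol rule filled it up to 5, given as not past the test. It also took up to 4 members with the smallest p of each list described, 13 fixed genes of load, calcineurin, cyclophilins, proliferation, matrix and cell types, and the 10 genes with the smallest larger p among those of opposite sign in VO against Sham and CsA against VO. Some genes that this rule takes are not reported here.

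GC content was taken from the longest transcript of each gene in the GENCODE M21 annotation. Of the gene identifiers, 99.93% were found there, and 98.33% of those had the same chromosome, start and end as in the deposited table, whose GRCm38 coordinates are printed. The correction removed, from each library, a loess trend (span 0.3, degree 1) of its deviation from the gene mean on GC, leaving out mitochondrially encoded genes. The position of CsA was the slope through the origin of CsA minus Sham on VO minus Sham, over the genes called in VO against Sham. Chance values for comparisons that share libraries came from 100 simulations of unchanged groups, with noise drawn independently for each gene and of equal spread in all libraries.

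Alternatives were pseudocounts of 0.1 and 0.5, no filter or a mean of at least 1 FPKM, median-of-ratios and quantile scaling, rescaling without mitochondrially encoded genes, no trend, robust empirical Bayes, library weights, only the groups compared, protein-coding genes only, genes of the X and Y left out, a replicate block, voom on the recovered fragments, a 2-fold requirement, and each library left out in turn. No library was left out of the main results. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

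The steps were tested on simulated data with 13477 genes and 100 changed genes per fold size. For VO against Sham, 61% of genes changed by a log2 of 1 and 99% of those changed by 2 were recovered, with 14 false calls. For CsA against VO these were 56% and 97%, with 13 false calls, and for CsA against Sham 71% and 98%, with 3 false calls. A simulated shifted list was found, and 1 of the other lists passed. The simulated noise was independent between genes and of equal spread in all libraries, with no GC trend and no library set apart. The changed genes had a mean log2 value above 2. These rates may therefore be too favourable for the real libraries and for low genes.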

Results

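RNA sequencing was used to profile right ventricular myocardium from wild-type C57BL/6 mice, which the labels place at postnatal day 7. The series covers 9 libraries in 3 groups of 3. Sham libraries came from the control operation, VO libraries from mice given a surgical fistula that loads the heart with extra blood volume, and CsA libraries from mice given the fistula and injections of cyclosporin A. Cyclosporin A binds cyclophilins and blocks the phosphatase calcineurin. Each library was made from 1 µg of total RNA and held between 12046288 and 15986747 fragments assigned to genes. The labels state neither the age at harvest nor that each library is a separate mouse, so the p-values measure only the spread between these samples, which may be technical. Of 54532 genes in the table, 13477 had a mean of at least 0.5 FPKM and were tested.

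Several libraries stood apart from the rest of their group. Myl7 (ENSMUSG00000020469, chromosome 11, 5896637 to 5898782 in GRCm38), the atrial myosin light chain, was at 235 and 269.7 FPKM in Sham 1 and Sham 3 and at 1.10 FPKM in Sham 2. In the CsA group Myl7 was at 68.3 FPKM in CsA 3 and at 13.2 and 0.959 FPKM in the other libraries, and the VO libraries lay between 3.02 and 6.06 FPKM. In VO 3, mitochondrially encoded genes took 11.01% of the fragments, against 22.18% to 26.34% in the other 8 libraries. The hemoglobin gene Hbb-bs reached 1304 FPKM in VO 3 and 391.1 to 593.2 FPKM elsewhere, and Fabp4, a fatty acid binding protein of capillary endothelium and fat, reached 455.8 FPKM against 110.7 to 174.7 FPKM. VO 3 also had 17003 genes above 0, against 19619 to 20479 in the others. Y-linked Ddx3y was at 18.6 FPKM in Sham 2 and at 0 in the other 8 libraries, while Xist, the transcript of the inactive X chromosome, was at 0.00401 FPKM in Sham 2 and at 10.17 to 66.28 FPKM elsewhere. By these transcripts Sham 2 looked male and the other 8 libraries female, so sex was not balanced between the groups. Leaving out genes of the X and Y does not remove an effect of sex on other genes.

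**Figure D1:**
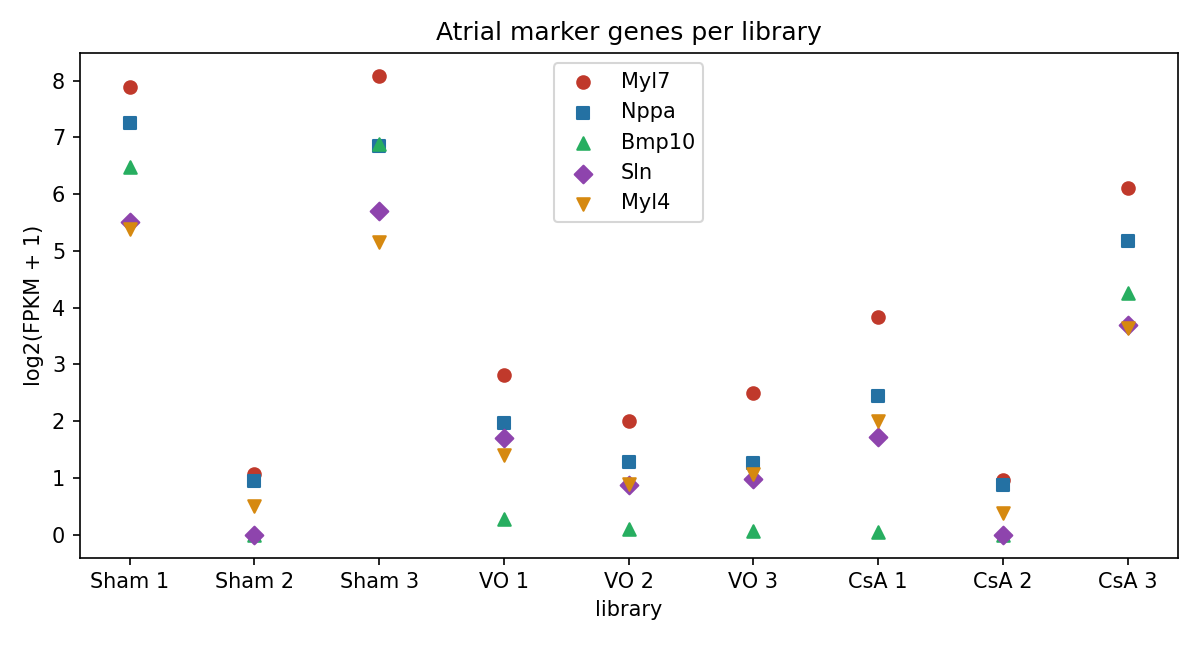
Expression of 5 atrial marker genes in each of the 9 libraries, as log2(FPKM + 1) on the vertical axis, with 1 point per gene and library. Sham 1, Sham 3 and CsA 3 have Myl7 at 235, 269.7 and 68.3 FPKM, while Sham 2 has 1.10 FPKM.

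The comparison of VO with Sham asked which transcripts differ in the right ventricle after the fistula. Transcripts of the replication factor Rfc4 and of the splicing factors Srsf7 and Snrpd1 were higher in VO, with fitted folds of 2.85 to 2.92 on the log2(FPKM + 1) scale. Those of the stress-response gene Ddit4 and the heart and muscle cytochrome oxidase subunit Cox8b fell. Rfc4 (ENSMUSG00000022881, chromosome 16, 23113943 to 23127737) stood at 13.6 ± 0.496 FPKM in VO and 4.06 ± 0.874 FPKM in Sham (SD, n = 3), a log2 fold change of 1.54 ± 0.239 (SE; limma adjusted p = 0.0382). Ddit4 (ENSMUSG00000020108, chromosome 10, 59949669 to 59951834), an inhibitor of mTORC1 signalling, stood at 7.53 ± 1.64 against 42.3 ± 15.9 FPKM, a log2 fold change of -2.28 ± 0.419 (limma adjusted p = 0.0382). In limma, 642 of 13477 genes passed an adjusted p of 0.05, 275 higher and 367 lower in VO, and 239 of them differed at least 2-fold. At an unadjusted p under 0.05 there were 3949 genes, and voom on the recovered fragments called 908. The libraries of the 2 groups did not overlap for 33.1% of tested genes. The average over all splits is 10%, but genes vary together, so a single split can differ from it.

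GC content differed between the called genes. The transcripts of genes higher in VO had a median GC of 42.0%, those of lower genes 57.3% and the others 49.4%, and across genes, which are not independent replicates, fold change and GC had a Spearman correlation of -0.53. The median log2 fold change went from 0.35 in the lowest of 10 equal groups of genes by GC to -0.44 in the highest. After a correction of each library for its GC trend, limma called 0 genes (2844 at an unadjusted p under 0.05; smallest adjusted p 0.0662). All 633 called genes with a GC value kept their sign, with Rfc4 at a log2 fold change of 1.33 ± 0.222 and Ddit4 at -1.94 ± 0.378. The fold was smaller in 593 of them, while Rps19bp1 (1.78 ± 0.257), Hmgn2 (1.63 ± 0.312), Phlda1 (1.69 ± 0.299) and Rpl23a (-2.79 ± 0.433) kept or gained theirs, at adjusted p of 0.0662 to 0.0789. The count of 642 genes also fell to 0 with no filter on low values and with only the Sham and VO libraries in the fit, and to 1 with the replicate number as a block. In settings chosen after the data were seen it was 0 with the atrial marker level as a covariate and 3 without Sham 1, Sham 3 and CsA 3, the libraries high in Myl7. Leaving out a library gave 1 gene without Sham 1 (Mir6931, chosen after its values were seen), 69 without Sham 2, 0 without Sham 3, VO 1, CsA 1 or CsA 3, 793 without VO 2, 761 without CsA 2 and 2032 without VO 3, of which 637 were among the 642.

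**Figure D2:**
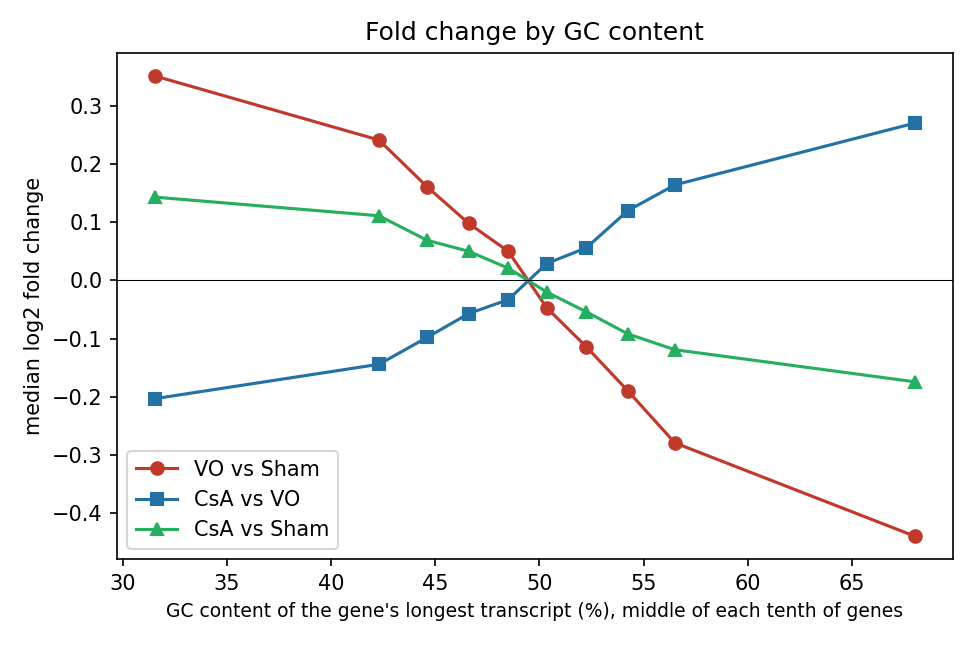
Median log2 fold change (vertical axis) of the tested genes in 10 equal groups ordered by the GC percent of the longest transcript (horizontal axis), for the 3 comparisons. VO against Sham goes from 0.35 to -0.44, CsA against VO from -0.20 to 0.27 and CsA against Sham from 0.14 to -0.17.

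Among the 8 genes with the highest fold in VO, Srsf7, a splicing factor of the SR family, stood at 51.3 ± 2.92 against 17.5 ± 3.04 FPKM (log2 1.51 ± 0.248, limma adjusted p = 0.0382), and Snrpd1, a core protein of spliceosomal particles, at 39.2 ± 14.6 against 12.5 ± 3.97 FPKM (log2 1.55 ± 0.341, adjusted p = 0.0408). Rps19bp1 had a log2 fold change of 1.49 ± 0.279, the nucleosome-binding protein Hmgn2 1.43 ± 0.31, the translation initiation factor Eif1a 1.32 ± 0.182 and Phlda1 1.3 ± 0.3 (adjusted p from 0.0382 to 0.0447). Stfa1, a cysteine protease inhibitor with near-identical copies, is uncertain: it had 70 fragments in VO and 3 in Sham, a ratio of 21 (95% interval 6.89 to 104, counting error only). Among the 8 lowest, Cox8b stood at 101.7 ± 66.8 against 462.3 ± 61.9 FPKM (log2 -2.44 ± 0.516, adjusted p = 0.0408) and Atp5k, a subunit of ATP synthase, at 15.8 ± 7.45 against 89.7 ± 15.7 FPKM (log2 -2.53 ± 0.402, adjusted p = 0.0382). Scand1 had a log2 fold change of -2.24 ± 0.483, Podn -2.09 ± 0.425 and the transcription factor Cebpb -1.93 ± 0.334. After the GC correction Scand1 was at -1.45 ± 0.334, Podn at -1.81 ± 0.415 and Cebpb at -1.195 ± 0.201 (adjusted p = 0.09, 0.0898 and 0.0662), with GC contents of 68.4%, 56.3% and 67.2%. Rpl23a, at -2.76 ± 0.431, is uncertain because 14 named pseudogene copies can share its reads. Ccl21a, a chemokine with near-identical copies, was at 0 in every VO library and at 1.15 to 5.8 FPKM in Sham, at least 7.6-fold lower against a floor of 3 fragments per library.

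None of the 13 genes fixed in advance passed the test in this comparison. The calcineurin target Rcan1 stood at 35.7 ± 11.9 FPKM in VO and 24.2 ± 2.98 FPKM in Sham (SD, n = 3; log2 0.50 ± 0.244, limma adjusted p = 0.2). Ppia, cyclophilin A, stood at 65.7 ± 20.3 and 32.5 ± 10.4 FPKM (log2 0.99 ± 0.283, adjusted p = 0.0646), and the mitochondrial cyclophilin Ppif at a log2 of 0.29 ± 0.201 (adjusted p = 0.367). The load-responsive natriuretic peptide Nppb had a log2 of 0.83 ± 0.784, the slow myosin Myh7 -0.47 ± 0.202, skeletal actin Acta1 0.06 ± 0.605 and the proliferation marker Mki67 0.90 ± 0.551. Nppa, also an atrial marker, stood at 1.92 ± 0.855 against 88.4 ± 78 FPKM. Among matrix and cell markers, Col1a1 was at -0.67 ± 0.251, Col3a1 at 0.02 ± 0.177, Postn at 0.35 ± 0.386, Cd68 at -0.24 ± 0.422 and Pecam1 at -0.35 ± 0.159. After the GC correction Col1a1 was at -0.28 ± 0.254, Myh7 at -0.19 ± 0.228 and Postn at -0.06 ± 0.328. Rcan1 (0.72 ± 0.217), Ppif (0.40 ± 0.172) and Acta1 (0.37 ± 0.607) had larger folds than before, and limma called 0 genes in that setting.

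At the preset correlation, the DNA replication and mitosis lists were higher in VO. The basement membrane, smooth muscle and endothelial lists were lower. Of 39 lists tested with camera, 10 passed in VO against Sham, 3 higher and 7 lower, and 0 did with an estimated correlation. Of 10 splits of the 6 libraries, 5 gave at least 10 lists, the real split included, so the count does not set the real groups apart. The DNA replication list was higher, with 28 of 28 members above 0 and a median log2 of 0.67 (camera adjusted p = 2.68e-06; adjusted p = 0.884 with an estimated correlation). Rfc4 rose and 27 members did not pass; adjusted over the list alone, 5 were higher. Pcna, the sliding clamp of DNA polymerase, had a log2 of 1.17 ± 0.299 and the primase subunit Prim1 1.14 ± 0.314. The cell cycle and mitosis list had 29 of 30 members above 0 and a median of 0.87 (camera adjusted p = 2e-04; adjusted p = 0.884 with an estimated correlation), with 0 members past the test and 0 adjusted over the list alone. The phosphatase Cdc25c was at 0.88 ± 0.262 and the spindle protein Nusap1 at 1.15 ± 0.378. The interferon response list had 22 of 25 members above 0 and a median of 0.45 (camera adjusted p = 0.011; adjusted p = 0.884 with an estimated correlation), with 0 members past the test and 0 adjusted over the list alone. Ifit2, an interferon-induced protein, was at 0.80 ± 0.247. The interferon response call was lost without VO 2 (adjusted p = 0.14) or VO 3 (adjusted p = 0.198), and the cell cycle and mitosis call without the 3 libraries high in Myl7 (adjusted p = 0.156). Over 29 settings the adjusted p ranged from 3.8e-10 to 0.00982 for DNA replication, from 7.2e-08 to 0.156 for cell cycle and mitosis and from 1.18e-06 to 0.315 for interferon response. The median GC of these lists was 49.2%, 46.2% and 47.4%, and after the GC correction their median log2 values were 0.72, 0.73 and 0.36.

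The lower calls for basement membrane, smooth muscle and endothelial lists held at the preset correlation only. All 14 members of the basement membrane list were below 0, with a median log2 of -0.50 (camera adjusted p = 0.000503; adjusted p = 0.884 with an estimated correlation). Col18a1, at -0.82 ± 0.173, and the laminin chain Lamb2, at -0.82 ± 0.201, fell and 12 members did not pass. Adjusted over the list alone, 6 were lower. In the smooth muscle and pericyte markers, 13 of 15 were below 0 with a median of -0.47 (camera adjusted p = 0.0103; adjusted p = 0.61 with an estimated correlation). Myh11, smooth muscle myosin, fell by 0.98 on the log2 scale, and the pericyte receptor Pdgfrb was at -0.92 ± 0.236. Adjusted over the list alone, 2 were lower. Of the endothelial and capillary markers, 19 of 25 were below 0 with a median of -0.35 (camera adjusted p = 0.0103; adjusted p = 0.884 with an estimated correlation). Plvap, at -0.90 ± 0.164, and the receptor Tie1, at -0.84 ± 0.186, fell and 23 did not pass. Adjusted over the list alone, 7 were lower. The call for endothelial and capillary markers was lost without VO 2 (adjusted p = 0.0805), and without the 3 libraries high in Myl7 (adjusted p = 0.244). After the GC correction the medians of the basement membrane, smooth muscle and endothelial lists were -0.35, -0.36 and -0.28, at a median GC of 55.5%, 53.6% and 52.2%. With the GC correction and VO 3 left out the basement membrane call was lost (adjusted p = 0.232). Over 29 settings the adjusted p ranged from 6.5e-06 to 0.232 for basement membrane, from 0.00113 to 0.244 for endothelial and capillary markers and from 0.00201 to 0.0426 for smooth muscle and pericyte markers.

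Among the glucocorticoid and circadian genes, 3 of 19 fell in VO, 3 adjusted over the list alone, with a median log2 of -0.29 (camera adjusted p = 0.0103; adjusted p = 0.884 with an estimated correlation). These were the clock gene Per1, at 2.95 ± 1.38 against 12.1 ± 1.54 FPKM (log2 -1.78 ± 0.239), Klf9 (-1.75 ± 0.382) and Dbp (-0.79 ± 0.16). In the list of calcium handling and ion channels, 2 of 24 fell and 3 adjusted over the list alone, with a median of -0.43 (camera adjusted p = 0.0189; adjusted p = 0.884 with an estimated correlation). Hrc, a calcium-binding protein of the sarcoplasmic reticulum, was at -1.25 ± 0.196 and Jph2, which couples that membrane to the T-tubules, at -1.09 ± 0.221. In the glycolysis list, the hexokinases Hk1 (-0.81 ± 0.17) and Hk2 (-0.68 ± 0.16) and the glucose transporter Slc2a4 (-0.89 ± 0.191) fell, 3 of 23 over all genes and 3 adjusted over the list alone (median -0.18, camera adjusted p = 0.0489; adjusted p = 0.884 with an estimated correlation). The atrial cardiomyocyte markers had 10 of 11 members below 0 and a median of -1.39 (camera adjusted p = 0.0189; adjusted p = 0.884 with an estimated correlation). Tbx5, an atrial and left ventricular transcription factor, fell by 1.26 on the log2 scale, and 2 members were lower adjusted over the list alone. Myl7 ranged 246-fold over the Sham libraries, and the atrial cardiomyocyte markers lost their call without Sham 1, Sham 3, VO 2 or VO 3 (adjusted p = 0.0719, 0.0836, 0.11 and 0.0806). Without the 3 libraries high in Myl7 the atrial cardiomyocyte markers turned higher in VO (adjusted p = 0.263). The calcium handling and ion channels call was lost without VO 2 or VO 3 (adjusted p = 0.11 and 0.0568). Glycolysis was past the threshold in 10 of 29 settings: it was lost without Sham 1, Sham 2, VO 1 or VO 2 (adjusted p = 0.0719, 0.069, 0.185 and 0.11), without CsA 1, CsA 2 or CsA 3 (0.0644, 0.0626 and 0.0574), and after the GC correction (0.34). Without the 3 libraries high in Myl7 the adjusted p was 0.263 for glucocorticoid and circadian genes and 0.211 for calcium handling and ion channels. Over the settings the highest adjusted p was 0.263, 0.211, 0.413 and 0.929 for the glucocorticoid, calcium, glycolysis and atrial lists, and the lowest 0.00164, 0.000854, 0.00147 and 2.49e-09.

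The other lists described in every comparison did not pass in VO against Sham. Fetal and stretch-response cardiac genes had a median log2 of 0.06 (camera adjusted p = 0.987), with 0 of 19 members past the test and 0 adjusted over the list alone. Tnni1, the fetal troponin I, was at 1.84 ± 0.601 and Xirp1 at -0.66 ± 0.197. Among fibrillar collagens and matrix genes, elastin (Eln) fell by 1.07 on the log2 scale as the 1 of 30 past the test, and 1 adjusted over the list alone (median -0.03, camera adjusted p = 0.222). In nuclear oxidative phosphorylation, Ndufb8, Cox8b and Atp5o fell, 3 of 37 members and 3 adjusted over the list alone, while the median was 0.02 and the test pointed down (camera adjusted p = 0.751). The mean score of nuclear oxidative phosphorylation was -0.50 and -0.36 in VO 1 and VO 2 and 0.70 in VO 3, against 0.004 to 0.10 in Sham, and without VO 3 the list passed as lower (camera adjusted p = 0.000158 at the preset correlation, with no estimated correlation run). Of the calcineurin and NFAT pathway, the catalytic subunit Ppp3cb rose (log2 0.81 ± 0.183) as the 1 of 20 past the test, with 2 higher and 2 lower adjusted over the list alone (median -0.07, camera adjusted p = 0.767). Among macrophage markers, the Fc receptor Fcgr1 rose (0.58 ± 0.127) as the 1 of 19 past the test, with 1 higher adjusted over the list alone (median -0.35, camera adjusted p = 0.707).

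**Figure D3:**
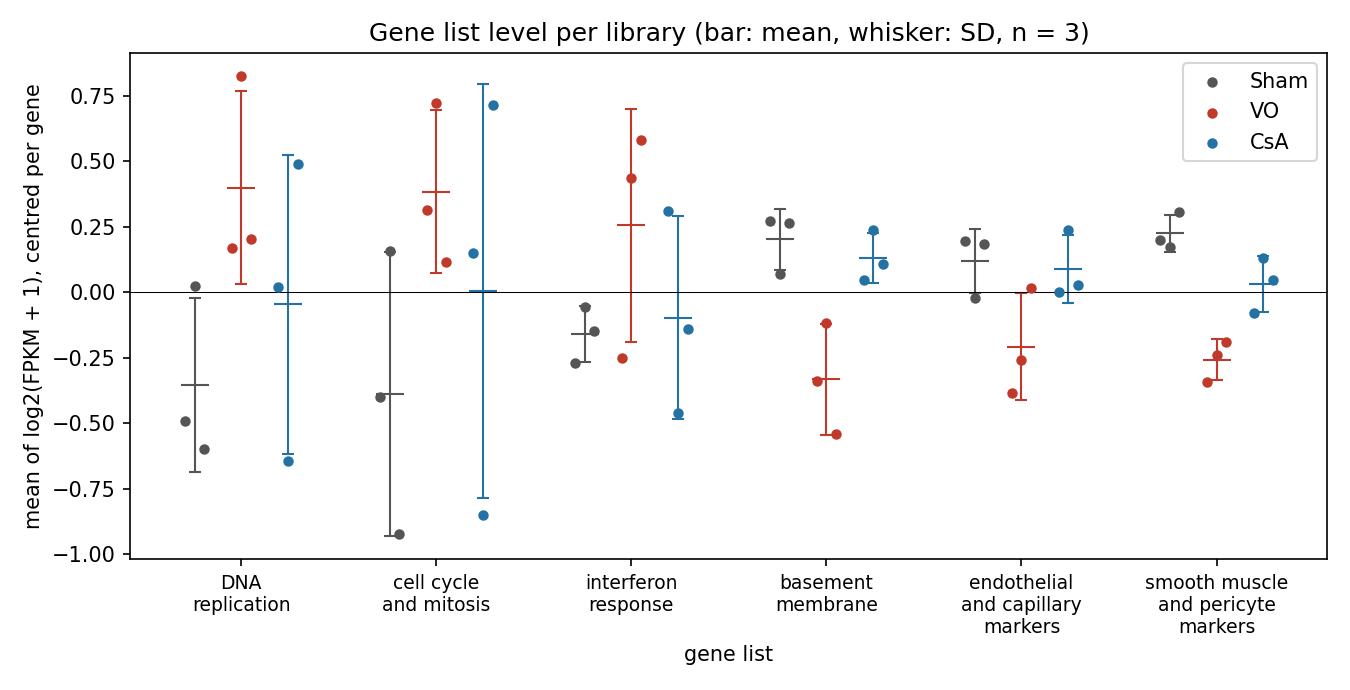
Level of 6 gene lists in each library, as the mean over members of log2(FPKM + 1) centred per gene (vertical axis), with points for libraries, bars for group means and whiskers for the SD (n = 3). The 3 VO libraries lie below the 3 Sham libraries for basement membrane and for smooth muscle and pericyte markers, and CsA libraries range from -0.65 to 0.49 for DNA replication.

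The comparison of CsA with VO asked what the drug changed after the same operation. No single gene passed, and the genes with the smallest p under the level and symbol rule for named genes included Klf4, Rasl10b and Dyrk1b with higher values in CsA. Stard3nl, Eif1a and Drg1 were among those with lower values. Klf4 (ENSMUSG00000003032, chromosome 4, 55527143 to 55532466), a transcription factor of endothelial and smooth muscle cells, stood at 15.6 ± 1.65 FPKM in CsA and 6.83 ± 1.18 FPKM in VO (SD, n = 3; log2 1.09 ± 0.158, limma adjusted p = 0.204). Ppia, cyclophilin A, stood at 32.8 ± 6.25 and 65.7 ± 20.3 FPKM (log2 -0.95 ± 0.283, limma adjusted p = 0.219). By list, basement membrane and endothelial genes were higher in CsA and DNA replication genes were lower (camera adjusted p = 6.16e-05, 0.00149 and 0.000671; adjusted p = 0.885, 0.908 and 0.908 with an estimated correlation). In limma 0 of 13477 genes passed (smallest adjusted p 0.122), 2219 had an unadjusted p under 0.05, and voom called 0 (2262 unadjusted). Non-overlapping libraries were seen for 21.2% of tested genes. The average over all splits is 10%, from which a single split can differ since genes vary together. Fold change and GC had a Spearman correlation of 0.40 across genes. Without VO 3, 1 gene passed, the microRNA gene Mir301 (log2 -1.93, limma adjusted p = 0.00264), which lies outside the rule for named genes and was chosen after its values were seen.

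The 5 highest genes by p also included the RAS-related Rasl10b (log2 0.97 ± 0.142), the kinase Dyrk1b (1.24 ± 0.201), Ralgds (0.97 ± 0.164) and Csrnp1 (0.77 ± 0.135), each at a limma adjusted p = 0.204. On the lower side were Stard3nl (-0.72 ± 0.131), Eif1a (-0.94 ± 0.182), Rbm12b2 (-0.94 ± 0.19), Drg1 (-0.97 ± 0.2) and the uncertain Stfa1, with 5 fragments in CsA and 70 in VO, a ratio of 0.0879 (95% interval 0.0277 to 0.215, counting error only). Rcan1 stood at 24.2 ± 5.61 against 35.7 ± 11.9 FPKM (log2 -0.52 ± 0.244, limma adjusted p = 0.32). Pecam1, an endothelial adhesion molecule, was at 0.43 ± 0.159 and Col1a1 at 0.54 ± 0.251 (adjusted p = 0.25 and 0.32). The other fixed genes were Ppif (-0.31 ± 0.201), Nppa (1.33 ± 1.556), Nppb (-0.67 ± 0.784), Myh7 (0.01 ± 0.202), Acta1 (-0.72 ± 0.605), Mki67 (-0.19 ± 0.551), Col3a1 (-0.05 ± 0.177), Postn (-0.08 ± 0.386) and Cd68 (0.35 ± 0.422), with adjusted p from 0.452 to 0.985.

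Of the 39 lists, 7 passed in CsA against VO, 4 higher and 3 lower, and 0 did with an estimated correlation; 0 members of any list passed by themselves. The 14 members of the basement membrane list were all above 0, with a median log2 of 0.50 (camera adjusted p = 6.16e-05; adjusted p = 0.885 with an estimated correlation) and 0 adjusted over the list alone. The perlecan gene Hspg2 was at 0.74 ± 0.241. Of the endothelial and capillary markers 20 of 25 were above 0 (median 0.27, camera adjusted p = 0.00149; adjusted p = 0.908 with an estimated correlation), 1 of them past the test adjusted over the list alone, with the junction cadherin Cdh5 at 0.83 ± 0.183. For glucocorticoid and circadian genes the median was 0.17 (camera adjusted p = 0.0234; adjusted p = 0.908 with an estimated correlation), 2 were higher adjusted over the list alone, and Per1 was at 1.27 ± 0.239 and Dbp at 0.79 ± 0.16. Mitochondrially encoded genes had 12 of 13 members above 0 (median 0.59, camera adjusted p = 0.0354; adjusted p = 0.908 with an estimated correlation) and 0 adjusted over the list alone, beside the low mitochondrial share of VO 3. All 28 DNA replication genes were below 0 (median -0.43, camera adjusted p = 0.000671; adjusted p = 0.908 with an estimated correlation), with 1 lower adjusted over the list alone and Rfc4 at -1.09 ± 0.239. The interferon response list had 24 of 25 below 0 (median -0.35, camera adjusted p = 0.00268; adjusted p = 0.908 with an estimated correlation) and 0 adjusted over the list alone, with the chemokine Cxcl10 at -0.67 ± 0.165. The cell cycle and mitosis list had 28 of 30 below 0 (median -0.40, camera adjusted p = 0.0305; adjusted p = 0.908 with an estimated correlation) and 0 adjusted over the list alone, with Cdc25c at -0.49 ± 0.262.

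Single libraries decided several of these calls. Without VO 2, the camera adjusted p was 0.0554 for endothelial and capillary markers, 0.0598 for glucocorticoid and circadian genes, 0.23 for DNA replication, 0.137 for interferon response and 0.484 for cell cycle and mitosis. Without CsA 2, DNA replication was at 0.132, interferon response at 0.103 and glucocorticoid and circadian genes at 0.157, and cell cycle and mitosis turned upward at 0.942. Without VO 3, interferon response was at 0.15 and mitochondrially encoded genes at 0.235, and the latter were at 0.184 without CsA 1. After the GC correction cell cycle and mitosis was at 0.0888. In that setting 5 of the 7 lists passed, the mitochondrial genes having no corrected value. Over up to 29 settings the highest adjusted p was 0.0653 for basement membrane, 0.0554 for endothelial and capillary markers, 0.157 for glucocorticoid and circadian genes, 0.473 for mitochondrially encoded genes, 0.23 for DNA replication, 0.279 for interferon response and 0.942 for cell cycle and mitosis. Lists that did not pass were fetal and stretch-response cardiac genes (median log2 -0.18, camera adjusted p = 0.459; Tnni1 -1.72 ± 0.601), fibrillar collagens and matrix (0.11, 0.148; Col5a1 0.47 ± 0.177), the calcineurin and NFAT pathway (0.07, 0.934; Ppp3cb -0.62 ± 0.183) and macrophage markers (0.24, 0.626; Fcgr1 -0.44 ± 0.127), with 0 members past the test in each and 0 adjusted over the list alone. Nuclear oxidative phosphorylation had a median of -0.07 where the test pointed up (camera adjusted p = 0.934), with 1 of 37 higher adjusted over the list alone and Ndufb8 at 1.02 ± 0.195. Without VO 3, where this list's mean score was 0.70, nuclear oxidative phosphorylation passed as higher (camera adjusted p = 3.16e-05), as did fibrillar collagens and matrix without CsA 2 (0.00387), both at the preset correlation.

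The comparison of CsA with Sham asked how far treated hearts differed from hearts without a fistula. No single gene passed. Under the level and symbol rule for named genes, the zinc finger genes Zfp758 and Zfp979 were among those with the smallest p for higher values, and Six5 and Gm8186 for lower ones. Zfp758 stood at 5.09 ± 0.654 FPKM in CsA and 3.11 ± 0.614 FPKM in Sham (SD, n = 3; log2 0.57 ± 0.163, limma adjusted p = 1). Zfp979 was at 0.59 ± 0.177, Zfp472 at 0.50 ± 0.173, the splicing protein Snrpg at 1.28 ± 0.445 and the receptor Lpar4 at 0.66 ± 0.228. Lower were Six5 (-0.50 ± 0.154), Gm8186 (-1.37 ± 0.426), B3gat3 (-0.52 ± 0.163), enteric smooth muscle actin Actg2 (-0.50 ± 0.157) and Obsl1 (-0.45 ± 0.146), all at an adjusted p of 1. Rcan1 stood at 24.2 ± 5.61 against 24.2 ± 2.98 FPKM (log2 -0.02 ± 0.244) and Ppia at 32.8 ± 6.25 against 32.5 ± 10.4 FPKM (log2 0.04 ± 0.283). The other fixed genes were Nppa (-2.17 ± 1.556), Nppb (0.17 ± 0.784), Myh7 (-0.46 ± 0.202), Acta1 (-0.66 ± 0.605), Ppif (-0.02 ± 0.201), Mki67 (0.71 ± 0.551), Col1a1 (-0.13 ± 0.251), Col3a1 (-0.03 ± 0.177), Postn (0.28 ± 0.386), Cd68 (0.11 ± 0.422) and Pecam1 (0.08 ± 0.159). In limma 0 of 13477 genes passed (smallest adjusted p 0.208), 200 had an unadjusted p under 0.05, and voom called 0 (119 unadjusted). The spread per gene was shared with the VO libraries, which differed most from each other by chi-square. With only the CsA and Sham libraries in the fit 562 genes had an unadjusted p under 0.05, and with library weights 3475, with 0 past the test in both. The lack of calls therefore does not show that CsA and Sham were alike. Libraries did not overlap for 9.7% of genes, where the average over all splits is 10%, and the Spearman correlation of fold and GC across genes was -0.53. Without Sham 1 the gene Mir6931 passed (log2 -2.41), and without Sham 2 Podn (-1.56), Hamp (-3.16) and Mir6931 (-1.78) did. Hamp and Mir6931 were chosen after their values were seen.

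Of the 39 lists, 7 passed in CsA against Sham and 0 with an estimated correlation, with 0 members past the test over all genes or adjusted over the list alone in each. All 30 members of cell cycle and mitosis (median log2 0.39, camera adjusted p = 3.44e-06; adjusted p = 0.837 with an estimated correlation) and all 28 of DNA replication (0.29, camera adjusted p = 3.44e-06; adjusted p = 0.837 with an estimated correlation) were above 0. Cenpe, a mitotic kinesin, was at 0.52 ± 0.314 and Prim1 at 0.67 ± 0.314. The 11 atrial cardiomyocyte markers were all below 0 (median -1.04, camera adjusted p = 3.44e-06; adjusted p = 0.743 with an estimated correlation), with Bmp10 at -3.02 ± 1.705, beside Myl7 at 235 and 269.7 FPKM in Sham 1 and Sham 3 and 68.3 FPKM in CsA 3. Also lower were calcium handling and ion channels (-0.19, camera adjusted p = 0.013; adjusted p = 0.743 with an estimated correlation; Jph2 -0.47 ± 0.221) and glycolysis (-0.16, camera adjusted p = 0.014; adjusted p = 0.743 with an estimated correlation; Slc2a1 -0.40 ± 0.174). Smooth muscle and pericyte markers (-0.16, camera adjusted p = 0.0202; adjusted p = 0.603 with an estimated correlation; Cnn1 -0.88 ± 0.3) and left ventricle and trabecular markers (-0.28, camera adjusted p = 0.0283; adjusted p = 0.603 with an estimated correlation) were lower too. The last list shares Tbx5 and Bmp10 with the atrial markers and was at an adjusted p of 0.563 on genes held by 1 list.

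Without CsA 3 the adjusted p was 0.719 for cell cycle and mitosis, 0.571 for DNA replication and 0.0616 for calcium handling and ion channels. Without Sham 3 it was 0.178 for cell cycle and mitosis, 0.0541 for calcium handling and ion channels and 0.178 for left ventricle and trabecular markers. Without the 3 libraries high in Myl7, cell cycle and mitosis and DNA replication were lower in CsA, and atrial cardiomyocyte markers turned higher in CsA. Sham 2 was then the lone Sham library, and by its Y-linked and Xist transcripts it differed in sex from the CsA libraries. Smooth muscle and pericyte markers were at 0.105 without CsA 1. Glycolysis, past the threshold in 20 of 29 settings, was lost without Sham 1, Sham 2, CsA 1 or CsA 2 (0.0614, 0.0534, 0.0559 and 0.0748). Left ventricle and trabecular markers, past in 16 of 29, were lost without Sham 1, VO 1 or CsA 1 too (0.0614, 0.0616 and 0.0728). After the GC correction 4 of the 7 lists passed, and those lost were smooth muscle and pericyte markers (median -0.03, adjusted p = 0.134), glycolysis (-0.08, 0.149) and left ventricle and trabecular markers (-0.13, 0.149). Over the settings the highest adjusted p was 0.719 for cell cycle and mitosis, 0.571 for DNA replication, 0.361 for atrial cardiomyocyte markers, 0.817 for calcium handling and ion channels, 0.191 for glycolysis, 0.352 for smooth muscle and pericyte markers and 0.781 for left ventricle and trabecular markers. Among lists that did not pass were fetal and stretch-response cardiac genes (median -0.12, camera adjusted p = 0.151; Myl4 -1.68 ± 1.202), fibrillar collagens and matrix (-0.002, 0.879; Eln -0.48 ± 0.23), nuclear oxidative phosphorylation (-0.07, 0.497; Ndufb8 -0.26 ± 0.195), the calcineurin and NFAT pathway (-0.01, 0.637; Nfatc2 -0.27 ± 0.122) and macrophage markers (-0.05, 0.951; Cx3cr1 0.24 ± 0.151), with 0 members past the test in each and 0 adjusted over the list alone. Fetal and stretch-response cardiac genes passed as lower without CsA 1 or CsA 3 (camera adjusted p = 0.022 and 0.00345 at the preset correlation). This list shares Nppa, Myl4 and Myl7 with the atrial cardiomyocyte markers.

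The last comparison asked whether genes that differed between VO and Sham lay closer to Sham in CsA, a question about cyclosporin A in the loaded right ventricle. Klf4 stood at 18.98 ± 1.64 FPKM in Sham, 6.83 ± 1.18 in VO and 15.6 ± 1.65 in CsA (SD, n = 3), and Rasl10b at 8.73 ± 1.27, 2.86 ± 0.227 and 6.57 ± 0.647 FPKM. Dyrk1b, Csrnp1, Ralgds, the scaffold Ppp1r9b, the linker histone H1fx and the actin-binding Ablim3 were also lowest in VO, while Stard3nl and the uncertain Stfa1 were high in VO. Each of these 10 genes passed in VO against Sham and had a limma adjusted p of 0.204 in CsA against VO, and CsA minus Sham ranged from -0.39 for Dyrk1b to 0.07 for Stfa1 on the log2 scale. For H1fx the log2 fold in VO against Sham was 0.025 with the GC correction and VO 3 left out. Of the 642 genes, 640 had the opposite sign of fold in CsA against VO, 610 of them with an unadjusted p under 0.05 in limma, and 630 lay between Sham and VO. Choosing genes by the same VO libraries gives many such genes by itself. In 20 simulations of unchanged groups, added after the data were seen, the 642 genes with the smallest p were taken. They held on average 563, 164 and 486 such genes (at most 580, 191 and 511). The simulations drew each gene independently, while these libraries share trends over many genes, so the maxima may be too low as bounds. They also set all groups alike, with equal spread in every library. A real effect of the operation with no effect of the drug was not simulated, so these counts do not show what a drug without effect would give. No gene passed in both comparisons (0 opposite, 0 the same way, 0 for independent lists; voom called 0 in CsA against VO).

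**Figure D4:**
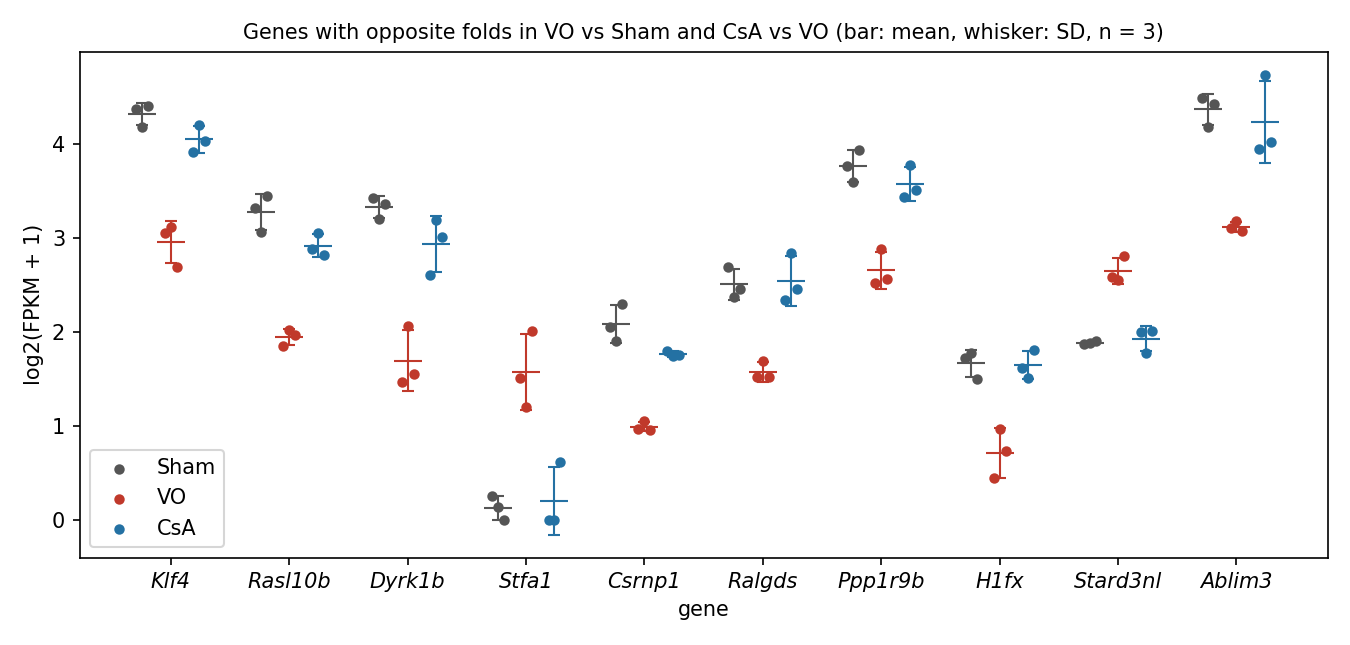
Levels of the 10 genes with the smallest p values of opposite sign in VO against Sham and CsA against VO, as log2(FPKM + 1) per library (vertical axis), with group means as bars and the SD as whiskers (n = 3). Klf4 stands at 18.98 FPKM in Sham, 6.83 FPKM in VO and 15.6 FPKM in CsA.

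Both comparisons share the VO libraries, which pulls their folds apart with no effect at all. Across genes the correlation was -0.895, against -0.499 in 100 simulations of unchanged groups (range -0.533 to -0.464), and the covariance was -0.159 against -0.0369. With shared Sham libraries, VO against Sham and CsA against Sham had a correlation of 0.666 against 0.503 and a covariance of 0.0711 against 0.0373, and no gene passed in both. On a scale from Sham at 0 to VO at 1, the slope over the 642 genes put CsA at 0.29. The CsA libraries lay at 0.48, 0.0709 and 0.319 (SD 0.206), and the correlation of their deviation with GC was -0.375, 0.289 and 0.148. Since GC parted the 642 genes, the position of CsA cannot be told apart from the GC trend of its libraries. The 20 simulations of unchanged groups gave 0.495 (range 0.433 to 0.558). They set all groups alike, so they do not give the position under a real effect of the operation and no effect of the drug. With VO 2 held out, and the other VO libraries at 1, CsA lay at 0.231 and VO 2 itself at 0.584, so CsA was at 0.395 of the way to VO 2 (793 genes, 93.4% of opposite sign in CsA against VO 2). With VO 3 held out CsA lay at 0.267 and VO 3 at 0.597, or 0.447 of the way (2031 genes, 66.1%), and with VO 1 held out no gene was called. Without Sham 2 the position was 0.591, over 69 genes, and without Sham 1 it was 1, from 1 gene. The covariance beyond the simulated one was -0.1225 with shared VO libraries and 0.0338 with shared Sham libraries. The simulations behind these correlations, covariances and the position drew each gene independently, with equal spread in all libraries. Their ranges leave out trends shared by genes and may be too narrow as bounds. The VO libraries differed most from each other by chi-square. A wider spread in VO by itself makes the correlation and covariance with shared VO libraries more negative and the position lower. The distance from the simulated values therefore cannot be read as an effect of the drug.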

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

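The GC and atrial settings, the GC correction with VO 3 left out or with a replicate block, and the GC correction with an estimated correlation were chosen after seeing the data; the other settings were planned. The cause was not tested where a value moved, except that leaving out libraries or groups leaves fewer samples to the fit. Genes called in VO against Sham numbered 642; they were 0 with no filter, with only the groups compared, with the GC correction alone, with the GC correction and the replicate block together, and with the atrial level as covariate. They were 1102 with protein-coding genes only, 239 at 2-fold, 19 with the GC correction and VO 3 left out, 3 without the atrial libraries, and 0 to 2032 without single libraries. CsA against VO gave 0 to 1 genes without single libraries and 1 with the GC correction and VO 3 left out (Mir301 in both); CsA against Sham gave 0 to 3 without single libraries, 1 with the atrial covariate (Mir6931) and 3 without the atrial libraries (Ddx3y, Eif2s3y and Mir6931, as without them in VO against Sham), where the lone Sham 2 is assumed to vary like the other groups. These genes were named after their values were seen.

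Of the lists, 10 passed in VO against Sham; 5 to 13 did without single libraries, 5 without the atrial libraries, 0 with an estimated correlation with or without the GC correction, 1 with fry and 23 with its mixed test. In CsA against VO 7 passed; 2 to 13 did without single libraries, 4 with the GC correction and block, and 0 with an estimated correlation, its GC-corrected form, fry or its mixed test. In CsA against Sham 7 passed; 5 to 10 did without single libraries, 11 with library weights, 4 with the GC correction, 3 on genes held by 1 list, and 0 with an estimated correlation, its GC-corrected form, fry or its mixed test.

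Genes changed in opposite ways numbered 0; they were 0 to 1 without single libraries, 1 with the GC correction and VO 3 left out, 524 at an unadjusted p under 0.01, and 373 against VO 3 when it was held out. Genes changed the same way in VO and CsA against Sham numbered 0; they were 0 to 3 without single libraries, 3 without the atrial libraries and 10 at an unadjusted p under 0.01. The position of CsA, 0.29, was 0.231 to 1 without single libraries (1 from a single gene without Sham 1), 1 without the atrial libraries (from Ddx3y, Eif2s3y and Mir6931, at 0 in every VO and CsA library left, which fixes it at 1), 0.154 with the replicate block (from Gm13192 alone), and had no value where no gene was called.

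Same-numbered libraries had correlations of -0.4 to 0.237 in their deviations from group means, and 2 of 9 libraries correlated best with their own number, so the numbers were not taken as pairs. The replicate block gave 1 gene in VO against Sham (Gm13192, named after its values were seen). Over 15254 values of named genes under 29 settings, 14307 kept their side of the threshold and direction or differed in sign with neither past (181). Another 784 lost and 162 gained the threshold, and H1fx reversed in VO against Sham (-0.95 to 0.025, GC correction with VO 3 left out). Of 529 named results only 56 were past the test. The rest had no call to lose, so all 784 losses fell on those 56. Of 56 named results past the test, 0 stayed past under every setting fixed in advance in limma and 0 after the GC correction. At 12046288 to 15986747 fragments, genes near the floor, such as Stfa1, rest on few fragments.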

Other observations

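The tests of symbol families, GC content, VO 3, atrial tissue, the operation, the cardiomyocyte share and unrelated differences between animals were chosen after the result was seen; the splits were planned. Genes were grouped by symbol stem, which gave 101 families with at least 12 tested members. In VO against Sham 3 passed camera and in CsA against VO 5, and 0 did with an estimated correlation (adjusted p = 0.991 and 0.999). The Rbm genes, RNA-binding proteins, had a median log2 of 0.27 in VO against Sham (23 of 33 above 0, camera adjusted p = 0.0172). Rbm12, Rbm12b2, Rbm7, Rbm39, the cold-inducible Rbm3 and Rbm18 rose, with log2 fold changes of 0.61 to 0.99, and Rbm38 fell by 0.99. In CsA against VO the Rbm median was -0.25 (camera adjusted p = 0.00231). The Snhg genes, hosts of small nucleolar RNAs, had a median of 0.42 in VO against Sham (10 of 12 above 0, camera adjusted p = 0.0172), with Snhg5 (1.12 ± 0.2) and Snhg1 (0.77 ± 0.176) past the test, and -0.33 in CsA against VO (camera adjusted p = 0.00231). The Arhgef genes, guanine nucleotide exchange factors, had a median of -0.37 in VO against Sham (18 of 21 below 0, camera adjusted p = 0.0103) and 0.34 in CsA against VO (camera adjusted p = 0.00294). The Klf transcription factors had a median of 0.41 in CsA against VO (9 of 12 above 0, camera adjusted p = 0.0198), and the Mettl methyltransferases -0.16 (camera adjusted p = 0.0472). After the GC correction 0 families passed in VO against Sham, and Rbm, Snhg and Klf did in CsA against VO (adjusted p = 0.0232, 0.0236 and 0.0232; adjusted p = 0.786, 0.965 and 0.965 with an estimated correlation).

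Other genes past the test in VO against Sham lay in lists that did not pass. Of the heat shock proteins Hsp90aa1 rose (log2 1.16 ± 0.252) and the co-chaperone Bag3 fell (-1.16 ± 0.2), and of the immediate early genes Klf4 (-1.36 ± 0.158) and the mRNA-decay factor Zfp36 (-1.32 ± 0.227) fell. Of the cyclophilins and permeability transition genes Ppid rose (0.73 ± 0.143) and the hexokinase Hk2, also in the glycolysis list that passed, fell (-0.68 ± 0.16). The invariant chain Cd74 (-1.33 ± 0.262), the fibroblast genes Mfap4 (-1.01 ± 0.222) and Pi16 (-1.36 ± 0.317), Hand2 (-1.19 ± 0.21), Chac1 (-1.22 ± 0.274) and Bbc3 (-0.94 ± 0.205) fell, while Lum rose (0.85 ± 0.206). The limma adjusted p of these genes lay between 0.0347 and 0.0482. Mt2, a metallothionein, was at 0 in all VO libraries and at 0.933, 0.245 and 5.64 FPKM in Sham 1, Sham 2 and Sham 3, and did not pass. Against a floor of 3 fragments per library, 0.337 FPKM, the Sham mean was at least 6.74-fold higher, a bound that rests on Sham 3, and Sham 2 lay below the floor.

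The genes called in VO against Sham were parted by GC content. VO 3 as the whole cause is excluded, since 637 of the 642 passed without it. Without VO 1, the library with the strongest GC trend, 0 genes passed. The count was also 0 without Sham 3, CsA 1 or CsA 3, so a leading part of VO 1 cannot be told apart from fewer libraries in the fit. A GC-dependent trend between libraries may account for part of the folds: the called genes kept a median share of 0.677 after the correction (quartiles 0.559 to 0.817), and the median absolute log2 fold went from 0.895 to 0.599 with a median SE of 0.186 before and 0.172 after. Of the 633 called genes with a GC value, 593 had a smaller fold and 568 a larger unadjusted p after the correction, and 65 had the same or a smaller unadjusted p. Genes at an unadjusted p under 0.05 went from 3949 to 2844, which makes the adjustment stricter for all of them. The trend as the whole cause cannot be told apart from an effect of the operation that follows GC, since the trend parted the groups. The correlation of a library's deviation with GC was 0.348 to 0.499 in Sham and -0.666, -0.354 and -0.002 in VO 1 to 3. Of the 10 splits of the 6 libraries, 1, the real one, gave as many genes (642, highest other 1), and 5 gave as many lists (10, highest other 15). The 10 splits are too few for a share under 0.05, and the count of 10 lists does not set the real split apart.

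Atrial cardiomyocyte markers were lower in VO and CsA than in Sham by camera (adjusted p = 0.884 and 0.743 with an estimated correlation). Without the 3 libraries high in Myl7 they turned higher in both (camera adjusted p = 0.263 and 0.191). Atrial tissue in Sham 1, Sham 3 and CsA 3 is a candidate explanation: over these libraries Myl7 ranged 3.95-fold, and the ratios of Sln, Bmp10, Nppa and Myl4 to it ranged at most 1.64-fold. The test of the operation as the whole cause stayed undecided. To count against it, at least 2 Sham libraries had to lie at or under the highest VO library, and only Sham 2 did. Libraries differed inside the groups, where the operation was the same. The mean score of the list was 2.11 and 2.14 in Sham 1 and Sham 3 but -1.14 in Sham 2, below all VO libraries. In the operated CsA group it was 0.896 in CsA 3, above all VO libraries, and -0.431 and -1.20 in CsA 1 and CsA 2. A part played by the operation cannot be told apart with these libraries, as 2 of 3 Sham libraries were above all VO libraries.

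DNA replication genes were higher in VO than in Sham by camera (adjusted p = 0.884 with an estimated correlation), with 1 of 28 members past the test over all genes. A GC-dependent trend as the whole cause is excluded, since the median log2 was 0.72 after the correction against 0.67 before. A lower share of cardiomyocytes was predicted to raise smooth muscle and pericyte markers. Their score was lower in VO by a difference of -0.485, beyond its SD of 0.07 in Sham and 0.078 in VO. This cannot decide the question, since the share of 1 other cell type can fall along with that of cardiomyocytes. The score of adult sarcomere genes was -0.436, -0.234 and 0.176 in VO 1 to 3, against 0.203, 0.196 and 0.016 in Sham 1 to 3. A difference between animals unrelated to the operation may remain, since the exact permutation p of the list score was 0.1, the smallest that 3 against 3 allow. The effect of the fistula stays among the open explanations.

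The other splits add the following values. For CsA against VO, 9 of 10 splits gave at least 7 lists (highest other 13), and for CsA against Sham 8 of 10 did (highest other 14). These splits are too few for a share under 0.05. Since most of them gave as many lists, the counts of 7 do not set the real groups apart. Where the real count of genes was 0 in limma, every split reaches it, so the number of splits decides nothing: 10 of 10 for CsA against VO (highest other 1) and 10 of 10 for CsA against Sham (highest other 93). The split with 93 genes set Sham 1, Sham 3 and CsA 2 against Sham 2, CsA 1 and CsA 3. Likewise, of 100 splits of the 9 libraries, 100 gave at least the 0 genes changed in opposite ways (highest other 92) and 100 at least the 0 changed the same way (highest other 75).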
